A study of Mus musculus with 10 samples.

How the data were processed

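Poly(A) RNA of C57BL/6 mouse skin was measured in 10 samples, 5 from mice with a basophil VAMP7 conditional knockout (CKO) and 5 from floxed controls (Flox), grouped as the labels give them. Libraries were made with random hexamers and read as single-end reads of DNA nanoballs, per the labels' protocols. The Cre driver, the time of sampling and whether each sample is a separate animal are not given in the sources used here. The series text also gives another number of samples than the 10 of the labels, which were followed.

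The authors deposited 1 table of FPKM values per gene, which are scaled to transcript length and to the mapped total of a library, per the file headers. Reads were aligned with HISAT, per the submitters' processing notes. The read counter, genome build, annotation and software versions are not given in the sources used here. No read counts were used, so the depth is unknown and no interval of counting error is given. How reads shared by close paralogs were assigned is not given either, so values of families such as Mcpt, Ear, Stfa and Sprr are uncertain. Of 19175 genes, 35 were 0 in every library.

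The test planned before the data were examined was for counts. Since the table holds FPKM, the planned fallback was used, limma-trend (limma 3.58.1 in R 4.3.3, robust off) on log2(FPKM + 1) of the 13186 genes with at least 1 FPKM in at least 5 libraries. Tests were two-sided, and adjusted p (limma) is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The pseudocount makes log2 fold changes of low genes too small. Groups, tests, gene lists and the rule for named genes were chosen before the data were examined.

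Of 31 gene lists, 30 had at least 3 tested members. The mitochondrial list had none. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation), which compares a list with other genes, and with fry, which asks whether its genes move on balance one way. The score of a list is the mean log2 value of its members in a library, tested by exact permutation over 252 assignments, where 0.00794 is the smallest p they can give. Adjustment was over the lists.

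Genes were named by rule. They were 9 fixed genes, per direction up to 10 genes of largest change that passed, filled with those of lowest p, and up to 4 members of lowest p per list described. Symbols without a gene name were left out. Some genes that the rule picks are not reported here, but they count in every list test. Which lists are described in the text, and how many members are named for each, was settled after the values were seen, as was the choice of 5 genes, Prss34, Per1, Tsc22d3, Zbtb16 and Klf9, and of 3 added lists.

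On simulated data of 13186 genes the test recovered 66%, 92%, 100% and 100% of 50 genes at log2 changes of 0.5, 1, 2 and 3, with 4 false calls. The simulated noise was normal, independent between genes and of equal spread in all libraries. In the data CKO replicate 1 had an array quality weight of 0.272, against 0.561 to 2.12 in the other libraries. Mcpt8, at a log2 fold change of -2.56, did not pass there (limma adjusted p = 0.0507). The simulated shares may therefore overstate what the test can find here. Alternatives tried were a pseudocount of 0.1, no filter on low values, array quality weights, quantile normalization, the replicate number as a block, each library left out in turn, and camera with an estimated correlation. Rescaling to equal totals and the muscle score as a covariate were added after the data were seen.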

Results

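Poly(A) RNA was sequenced from the skin of C57BL/6 mice in the MC903 dermatitis model. MC903 (calcipotriol) is a vitamin D analogue that causes an itchy, type 2 inflammation when put on skin. The series compares 5 skin samples from mice with a conditional knockout of Vamp7 in basophils (CKO) with 5 from floxed controls (Flox). VAMP7 is a SNARE protein of vesicle membranes that takes part in secretion. The comparison asks which transcripts of inflamed skin differ when basophils carry the knockout. All 10 samples were from the MC903 model, so the effect of MC903 itself cannot be read from them. Gene values were FPKM for 19175 genes, of which 13186 had at least 1 FPKM in at least 5 libraries and were tested. The values of a library summed to 525369 to 581022 FPKM, and 17418 to 17592 genes were above 0. The number of reads is unknown. Errors below are SD with n = 5 per group for FPKM, and log2 fold changes are CKO against Flox on the log2(FPKM + 1) scale, which understates changes of low genes. The samples are numbered but not stated to be separate animals, so p-values measure the spread between these samples, which may be technical.

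Vamp7 (Entrez 20955), the targeted gene, was at 17.3, 19.2, 18.4, 18.8 and 17.7 FPKM in the CKO libraries and at 18.5, 22.5, 18.1, 19.2 and 19.4 FPKM in the Flox libraries. The groups overlapped, with a log2 fold change of -0.088 (SE 0.060) and a 95% interval of -0.22 to 0.045 (limma adjusted p = 0.530). The RNA came from whole skin, in which cells other than basophils express Vamp7, so these values do not check the label of a library. Of the 24 tested genes of Vamp7 and other vesicle fusion proteins, 0 passed over all genes tested. Adjusted over the list alone, 1 was higher and 2 were lower in CKO. These were Stxbp3, with a log2 fold change of 0.30 (SE 0.061), Vamp3 at -0.15 (SE 0.040) and Ankrd27, a VAMP7-binding protein, at -0.20 (SE 0.055). The median of the list was -0.069 (camera adjusted p = 0.286), -0.044 without CKO replicate 1 and -0.025 with the muscle score of each library as a covariate.

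Of the 8 genes that fell in CKO skin, 3 belong to a list of basophil markers, Cd200r3, Gata2 and Itga2b. Cd200r3, an activating receptor of basophils and mast cells, fell from 20.2 ± 1.33 FPKM in Flox to 7.83 ± 2.50 in CKO, a 2.58-fold lower mean (log2 fold change -1.31 (SE 0.18), adjusted p = 0.0463). Gata2, a transcription factor of the basophil and mast cell lineages, fell from 26.8 ± 2.62 to 12.2 ± 3.39 FPKM (log2 fold change -1.11 (SE 0.16), adjusted p = 0.0463). Itga2b, the integrin CD41, fell from 14.2 ± 1.44 to 6.68 ± 1.69 FPKM (log2 fold change -1.01 (SE 0.14)). Hrh4, the histamine H4 receptor, fell from 3.60 ± 0.444 to 1.35 ± 0.496 FPKM (log2 fold change -0.99 (SE 0.14)). The lowest adjusted p, 0.0164, was that of the water and glycerol channel Aqp9, which fell from 17.8 ± 0.491 to 9.15 ± 1.39 FPKM (log2 fold change -0.90 (SE 0.092)). The ATP-gated channel P2rx1 also fell, by 0.75 on the log2 scale, as did the kinase Tec, which fell by 0.47, and the acyltransferase Mboat1, which fell by 0.41. In all, 8 genes fell and 6 rose (limma, adjusted p under 0.05), and the CKO and Flox libraries did not overlap for any of these 14 genes. Over all genes tested the groups did not overlap for 4.23%, against 0.794% by chance.

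The genes that rose were Jaml, an adhesion molecule of leukocytes, from 20.5 ± 1.58 FPKM in Flox to 36.0 ± 4.80 in CKO (log2 fold change 0.78 (SE 0.088), adjusted p = 0.0214), and Jdp2, a bZIP factor that dimerizes with Jun proteins, from 20.6 ± 2.72 to 34.1 ± 4.72 FPKM (log2 fold change 0.70 (SE 0.11)). Sla, an adaptor of antigen receptor signalling, rose by 0.66 on the log2 scale and Klhl6, a ubiquitin ligase adaptor of lymphoid cells, by 0.59. Bcl2l1, which encodes the survival protein BCL-XL, rose by 0.53 and Phlda1 by 0.47. The named genes of next lowest p did not pass. Fkbp5, a glucocorticoid-induced gene, was at 38.0 to 82.6 FPKM in CKO and 19.3 to 32.6 in Flox (adjusted p = 0.0511), and Fosl1, an AP-1 factor, at 5.19 ± 1.36 and 2.14 ± 0.696 (adjusted p = 0.0651). Chka and Spsb1 had log2 fold changes of 0.43 (SE 0.072) and 0.60 (SE 0.10), and on the lower side Pik3r3 had -0.40 (SE 0.063) (adjusted p = 0.0507). Of the genes fixed beforehand as readouts of the model, Tslp, the epithelial cytokine that MC903 induces, was at 96.5 ± 45.4 FPKM in CKO and 91.3 ± 7.48 in Flox. The vitamin D target Cyp24a1 was at 471 ± 145 and 444 ± 89.9 FPKM. The barrier gene Flg was at 25.7 ± 7.97 and 24.6 ± 5.79, and the wound keratin Krt6a at 1759 ± 118 and 1758 ± 208. Their 95% intervals spanned -0.57 to 0.51, -0.38 to 0.50, -0.44 to 0.51 and -0.20 to 0.22 on the log2 scale, so no direction is given for them.

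The counts of 6 and 8 genes moved with single libraries. With FPKM rescaled to equal library totals, 2 genes rose and 6 fell, and with the muscle score of each library as a covariate 0 passed, against 1267 at an unadjusted p under 0.05 in limma; the median absolute log2 fold change of the 14 genes was 0.68 there and 0.73 without the covariate. Without 1 library, the counts higher and lower were 11 and 15 for CKO replicate 1, 8 and 1 for replicate 2, 1 and 4 for replicate 3, 1 and 2 for replicate 4, 1 and 4 for replicate 5, and 4 and 1 for Flox replicate 4. Without any 1 of Flox replicates 1, 2, 3 and 5 both counts were 0 in limma, with 1498 to 1822 genes at an unadjusted p under 0.05, against 1993 with all libraries. The 14 genes kept their sign in each of these fits. Without 1 library no other outcome was possible, since the groups did not overlap for these genes.

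Markers of basophils were lower as a group. All 12 tested members of the list had a negative log2 fold change, with a median of -1.03. Of these, 3 fell over all genes tested and 9 fell adjusted over the list alone. The 3 members that did not pass over the list alone had log2 fold changes of -0.18 to -0.032. Mcpt8 (Entrez 17231), the basophil granule protease, was at 6.56 to 43.2 FPKM in the CKO libraries and 116 to 159.6 in the Flox libraries, a 5.17-fold lower mean (log2 fold change -2.56 (SE 0.41)). Its adjusted p was 0.0507 over all genes and 1.59e-04 over the list alone. Cyp11a1, a steroidogenic enzyme also found in basophils and mast cells, was at 19.2 ± 5.00 FPKM in CKO and 40.2 ± 3.65 in Flox (adjusted p = 0.0507 over all genes and 1.59e-04 over the list alone). The list was lower than other genes by camera (adjusted p = 1.24e-09), a call that was lost with an estimated correlation (adjusted p = 0.355 with an estimated correlation). The fry test of the list had an adjusted p of 0.0140, and no other list passed fry. The list score was 4.00 ± 0.346 in CKO and 4.88 ± 0.0740 in Flox, without overlap (exact permutation p = 0.00794, the smallest the design allows, and 0.179 after adjustment over the lists). At that smallest p, 1 list alone cannot pass the adjustment over the lists. Skeletal muscle genes were higher in the same CKO samples (median log2 fold change 0.87), and basophil list members lay a median of -0.62 from the other CKO libraries in CKO replicate 1. The median of 9 mast cell genes was 0.0075 and their mean -0.092 (camera adjusted p = 0.765). The median turned to -0.010 after rescaling to equal totals, and to -0.011, -0.022 and -0.064 without CKO replicate 1, CKO replicate 2 and Flox replicate 5. The members of lowest p were Mcpt1, with a log2 fold change of -0.61 (SE 0.20), and Cma2 at -0.45 (SE 0.21), and 0 passed over all genes or adjusted over the list alone.

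**Figure D1:**
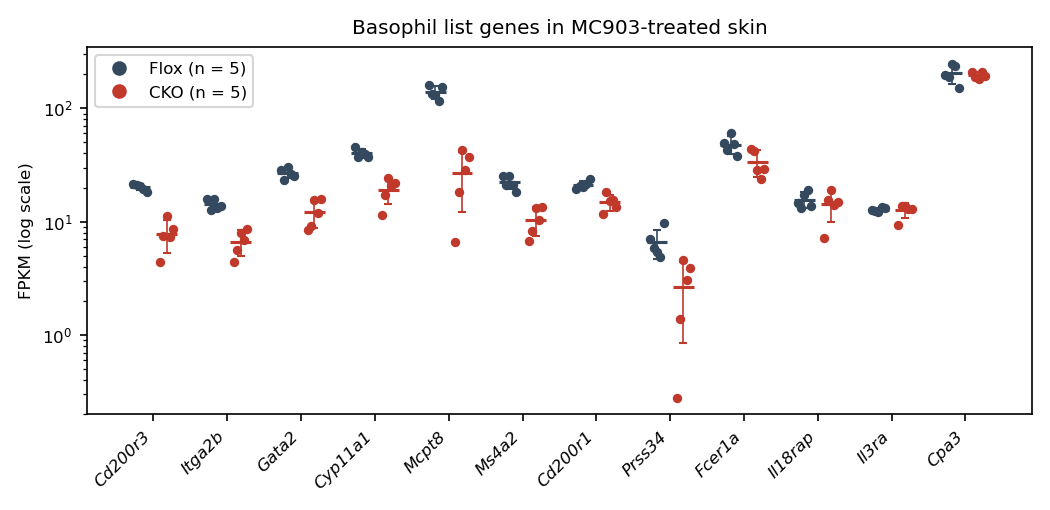
FPKM (log axis) of the 12 tested basophil list genes in each library, with the mean and SD of 5 CKO and 5 Flox libraries. Mcpt8 lay at 6.56 to 43.2 FPKM in CKO and 116 to 159.6 in Flox.

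Among 25 tested genes of type 2 immunity, 19 had a negative log2 fold change, and 0 passed over all genes tested. Adjusted over the list alone, 4 were lower and 2 higher in CKO. Il4, the cytokine that drives type 2 responses, was at 3.49 ± 1.57 FPKM in CKO and 8.67 ± 2.32 in Flox, a 2.48-fold lower mean without overlap (log2 fold change -1.15 (SE 0.24), adjusted p = 0.0845 over all genes and 0.00485 over the list alone). The eosinophil chemokine Ccl24 was at 23.0 ± 6.08 and 59.3 ± 19.0 FPKM (log2 fold change -1.31 (SE 0.23)), and the lipoxygenase Alox15 at 6.74 ± 2.51 and 14.1 ± 2.10 (log2 fold change -1.02 (SE 0.21)). Areg, a growth factor of type 2 tissue repair, went the other way, at 28.2 ± 5.81 FPKM in CKO and 18.6 ± 1.83 in Flox (log2 fold change 0.56 (SE 0.12)). Il13 was low in both groups, at 0.768 ± 0.395 and 1.52 ± 0.690 FPKM, and did not pass either adjustment. The median of the list was -0.21 and camera gave an adjusted p of 0.209 (adjusted p = 0.762 with an estimated correlation). Without CKO replicate 4 the list passed camera, with a median of -0.29 and an adjusted p of 0.0348, and over all alternatives its adjusted p was 0.0239 to 0.762.

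Eosinophil genes had a median log2 fold change of -0.40 (camera adjusted p = 0.0123, and adjusted p = 0.601 with an estimated correlation). Of 8 tested genes, 7 had a negative log2 fold change, 0 passed over all genes tested, and 3 fell adjusted over the list alone. These were Siglecf, the eosinophil lectin, at 1.93 ± 0.322 FPKM in CKO and 3.78 ± 0.928 in Flox (log2 fold change -0.69 (SE 0.13)), the eotaxin receptor Ccr3 at 1.75 ± 0.406 and 3.83 ± 1.13 (log2 fold change -0.79 (SE 0.16)), and the ribonuclease Ear6 at 2.71 ± 0.428 and 4.19 ± 1.03. Prg2, which encodes major basic protein, was at 2.46 ± 1.30 and 4.61 ± 2.27 FPKM. With array quality weights the camera call was lost (median -0.32, adjusted p = 0.0775; 0.00150 to 0.601 over all alternatives). Skeletal muscle genes were higher in the same CKO samples (median 0.87), and with the muscle score as a covariate the eosinophil median was -0.62 (adjusted p = 0.00831; 0.00150 to 0.601 over all alternatives). Among 15 genes of itch and IgE pathways, Hrh4 fell over all genes tested, and 2 fell and 1 rose adjusted over the list alone. The second of the lower genes was the prostaglandin E2 receptor Ptger3, at 4.04 ± 0.798 FPKM in CKO and 6.31 ± 0.462 in Flox (log2 fold change -0.55 (SE 0.10)). The median of this list was -0.12 (camera adjusted p = 0.778), -0.061 without CKO replicate 1 and -0.043 with the muscle covariate.

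Genes of innate inflammation moved in both directions. Il6 was lower in CKO, at 12.5 ± 2.61 FPKM against 20.2 ± 1.91 in Flox (log2 fold change -0.66 (SE 0.13), adjusted p = 0.0739 over all genes and 0.00929 over the list alone). In the same list the prostaglandin synthase Ptgs2 was at 43.9 ± 8.31 FPKM in CKO and 24.6 ± 5.90 in Flox, the signalling inhibitor Socs3 at 69.8 ± 9.67 and 49.2 ± 9.36, and the granulocyte growth factor Csf3 at 8.46 ± 4.39 and 3.23 ± 0.702. Of 26 inflammatory genes, 0 passed over all genes tested, while 4 rose and 1 fell adjusted over the list alone. The list median was 0.21 (camera adjusted p = 0.00502, and adjusted p = 0.762 with an estimated correlation). The neutrophil list had a median of 0.44 over 18 genes (camera adjusted p = 0.00251, and adjusted p = 0.762 with an estimated correlation). In it 0 genes passed over all genes tested and 1 rose adjusted over the list alone, the decoy receptor Il1r2, at 175 ± 39.6 FPKM in CKO and 106 ± 21.5 in Flox. The neutrophil collagenase Mmp8 was at 11.5 ± 4.44 and 6.66 ± 2.35 FPKM. The type 17 list had a median of 0.13 over 16 genes (camera adjusted p = 0.0192, and adjusted p = 0.355 with an estimated correlation). Of its members 0 passed over all genes tested, and 1 rose adjusted over the list alone, the antimicrobial peptide gene Defb3 at 32.9 ± 10.1 FPKM in CKO and 14.7 ± 6.41 in Flox. Lcn2, an iron-sequestering protein of inflamed epithelium, was at 95.3 ± 40.1 and 52.5 ± 10.8 FPKM. In CKO replicate 1 the members lay a median of -0.91 (neutrophil) and -0.59 (inflammatory) from the other CKO libraries. The camera call of the inflammatory list was lost without CKO replicate 2 (median 0.025, adjusted p = 0.375) and without CKO replicate 3 (median 0.090, adjusted p = 0.0892), that of the neutrophil list without CKO replicate 2 (median 0.17, adjusted p = 0.0985), and that of the type 17 list without CKO replicate 3 (median 0.066, adjusted p = 0.1001) or Flox replicate 5 (median 0.12, adjusted p = 0.0820). With the muscle covariate the medians were 0.57 (inflammatory), 0.82 (neutrophil) and 0.43 (type 17). CKO replicate 1, with the highest muscle score (6.04), weighs most on these covariate values. The call held but the median moved to 0.32 (inflammatory) and 0.29 (type 17) without CKO replicate 1, 0.27 (neutrophil) without CKO replicate 3, 0.19 (type 17) without CKO replicate 5 and 0.14 (inflammatory) without Flox replicate 5. Over all alternatives the adjusted p of these lists was 7.36e-11 to 0.762, 7.36e-11 to 0.762 and 7.34e-04 to 0.355.

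Skeletal muscle genes were higher in CKO samples, and most so in CKO replicate 1. All 19 tested members had a positive log2 fold change with a median of 0.87, 0 passed over all genes tested, and 15 rose adjusted over the list alone (camera adjusted p = 7.21e-14, and adjusted p = 0.565 with an estimated correlation). Skeletal actin Acta1 was at 279 FPKM in CKO replicate 1, 80.3 to 163 in the other CKO libraries and 41.5 to 89.4 in Flox. The fast myosin Myh1 was at 125.6 FPKM in CKO replicate 1 and 9.97 to 18.5 in Flox, and Myh2 and Tnnt3 had log2 fold changes of 0.74 (SE 0.24) and 1.04 (SE 0.35). The median was 0.60 without CKO replicate 1. The genes of the list took 0.366% of the FPKM total of CKO replicate 1, 0.0972% to 0.233% of that of the other CKO libraries and 0.0638% to 0.113% of that of the Flox libraries, so that CKO replicate 2, the lowest, lay within the Flox range. CKO replicate 1 also stood apart in interferon-induced genes. The interferon-induced chemokine Cxcl10 was at 0.770 FPKM there and 34.4 to 130.4 FPKM in the other CKO libraries. Over all 10 libraries the 27 interferon genes had a median of -0.081 (camera adjusted p = 0.720, with the opposite sign of test), and 0 passed over all genes or adjusted over the list alone. Without CKO replicate 1 the median was 0.55 (camera adjusted p = 1.05e-09, and exact permutation p of the score 0.190) and without Flox replicate 4 it was 0.091 (adjusted p = 0.283), with 1.12e-14 to 0.971 over all alternatives. With array quality weights (0.27) and with the muscle covariate (1.30) the list passed camera with a positive median. CKO replicate 1 had the lowest quality weight, 0.272, and the highest muscle score, 6.04. These 2 settings are therefore not separate from leaving that library out. Ifng and Cxcl9 had log2 fold changes of -0.24 (SE 0.31) and -0.44 (SE 0.87).

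**Figure D2:**
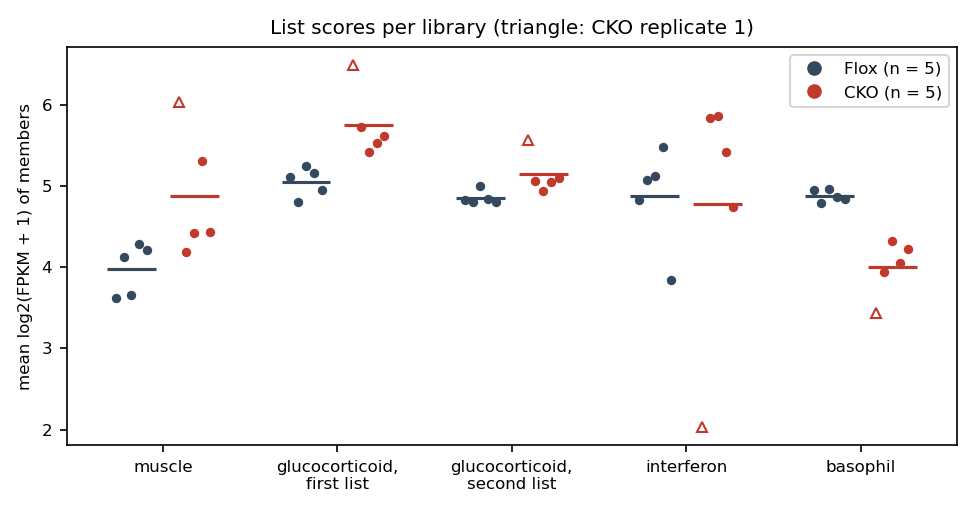
Mean log2(FPKM + 1) of the members of 5 gene lists in each of 5 Flox and 5 CKO libraries, with group means as lines and CKO replicate 1 as a triangle; both glucocorticoid lists were added after the data were examined. CKO replicate 1 had the highest muscle score, 6.04, and the lowest interferon score, 2.03.

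Cell cycle genes were lower in CKO by a small amount. All 26 members had a negative log2 fold change, with a median of -0.22 (camera adjusted p = 2.51e-08, and adjusted p = 0.607 with an estimated correlation). Of these, 0 passed over all genes tested and 3 fell adjusted over the list alone. Mki67, the Ki-67 antigen, was at 11.4 ± 1.52 FPKM in CKO and 14.7 ± 0.882 in Flox, and the kinetochore protein Cenpf at 1.73 ± 0.304 and 2.44 ± 0.278. The mitotic kinesin Kif11 had a log2 fold change of -0.34 (SE 0.10), and Ccna2, which did not pass, -0.27 (SE 0.086). Immediate early genes were higher, with a median of 0.19 over 22 genes (camera adjusted p = 1.60e-04, and adjusted p = 0.414 with an estimated correlation). In this list 0 passed over all genes tested and 4 rose adjusted over the list alone. They were Fosb, at 2.71 ± 1.31 FPKM in CKO and 0.894 ± 0.415 in Flox, Jund at 53.4 ± 4.92 and 43.6 ± 2.61, Klf2 at 23.6 ± 3.13 and 18.4 ± 1.71, and Jun at 30.3 ± 3.70 and 24.1 ± 1.85. The muscle list was higher in the same samples (median 0.87), and in CKO replicate 1 proliferation members lay a median of -0.35 from the other CKO libraries. Without CKO replicate 1 the proliferation median was -0.14, with the muscle covariate -0.14 and with array quality weights -0.13, and without CKO replicate 2 the immediate early median was 0.11.

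In the epidermis, basal keratinocyte genes had a median of 0.061 over 12 genes (camera adjusted p = 0.00251, and adjusted p = 0.607 with an estimated correlation). Of these, 0 passed over all genes tested and 3 rose adjusted over the list alone, among them the laminin chain Lamb3, at 11.9 ± 0.610 FPKM in CKO and 9.85 ± 0.843 in Flox, and the integrin Itga3, with a log2 fold change of 0.27 (SE 0.081). The basal median was 0.0021 without CKO replicate 1 and 0.019 without Flox replicate 4, and 0.13, 0.13 and 0.11 without CKO replicate 2, CKO replicate 3 and Flox replicate 2. With the muscle score as a covariate it was -0.085 (camera adjusted p = 0.381; 3.04e-04 to 0.607 over all alternatives). Among 32 wound keratinocyte genes 0 passed over all genes tested. Adjusted over the list alone, Fosl1 and the urokinase receptor Plaur, with a log2 fold change of 0.67 (SE 0.16), rose and the connexin Gjb2, at -0.28 (SE 0.072), fell. The list median was -0.0051 (camera adjusted p = 0.338). The 39 barrier genes had a median of -0.026 (camera adjusted p = 0.765) and the 10 genes of the vitamin D list 0.028 (camera adjusted p = 0.286), with 0 members past either adjustment. The vitamin D median was -0.0014 without CKO replicate 1, 0.095 without CKO replicate 5 and -0.061 with the muscle covariate. Of 19 macrophage and monocyte genes 0 passed over all genes tested. Adjusted over the list alone, Adgre1, which encodes F4/80, fell (33.3 ± 4.77 FPKM in CKO, 47.3 ± 6.26 in Flox) and the efferocytosis receptor Mertk rose (21.0 ± 1.13 and 17.8 ± 1.42). Their list had a median of -0.0018 (camera adjusted p = 0.273). The medians of the wound keratinocyte, barrier and macrophage lists were negative where camera gave a positive direction, and the means of the wound keratinocyte and macrophage lists were positive. These 3 medians turned positive without 1 library, the wound keratinocyte list without CKO replicate 3 or 4 or Flox replicate 1, 2 or 3 (up to 0.043), the barrier list without CKO replicate 2 or 3 or Flox replicate 1 or 2 (up to 0.065), and the macrophage list without CKO replicate 1 or 3 or Flox replicate 1, 4 or 5 (up to 0.056). T, NK and innate lymphoid genes had a median of -0.11 (camera adjusted p = 0.765) and dendritic and Langerhans cell genes -0.19 (camera adjusted p = 0.0611), with 0 members past either adjustment. With the muscle covariate the wound keratinocyte (0.10), macrophage (0.12) and T, NK and innate lymphoid (0.12) lists passed camera with positive medians. Without CKO replicate 1 the T, NK and innate lymphoid median was 0.086 (exact permutation p of the score 0.532, camera adjusted p = 0.0321; 0.00831 to 0.951 over all alternatives). The dendritic and Langerhans median was -0.0061 without CKO replicate 1 (camera adjusted p = 0.649), and the list passed camera without CKO replicate 2 (adjusted p = 0.0356), CKO replicate 3 (0.0155), CKO replicate 4 (0.00363) or Flox replicate 3 (0.0312), with 0.00363 to 0.937 over all alternatives.

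**Figure D3:**
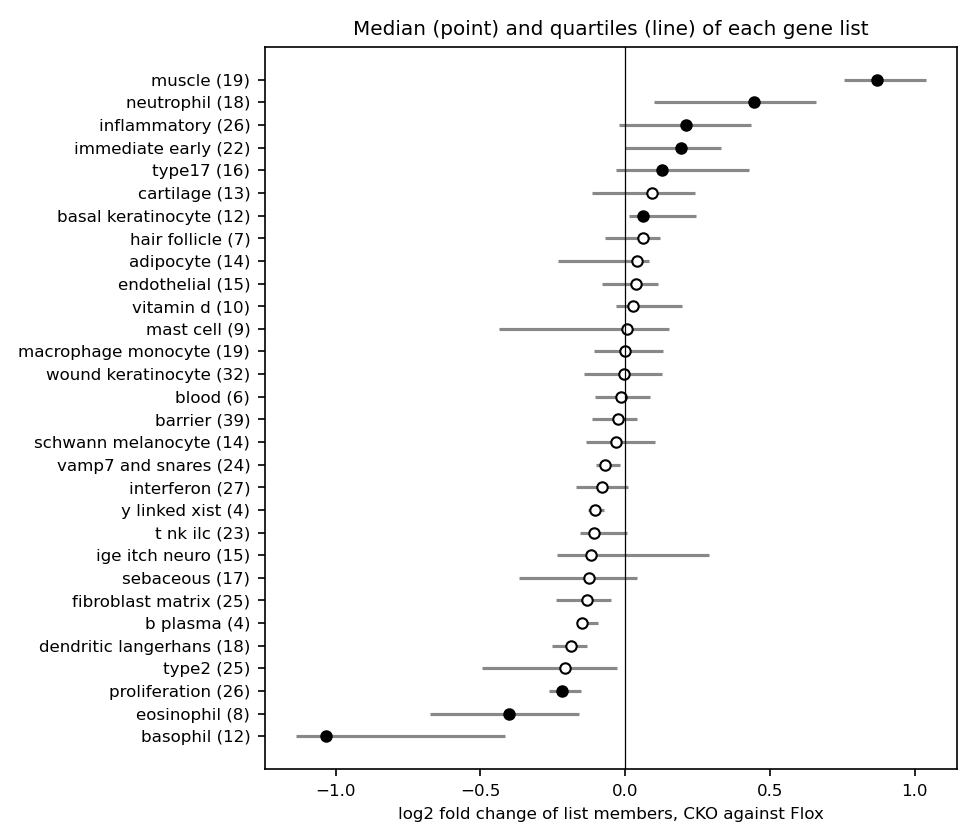
Median (point) and quartiles (line) of the log2 fold change of the tested members of each of 30 gene lists, CKO against Flox, with the number of members in brackets and filled points for camera adjusted p under 0.05 at the preset correlation. The medians ran from -1.03 for the basophil list to 0.87 for the muscle list.

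Of 30 lists, 9 passed camera at the preset correlation, 6 higher and 3 lower in CKO, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.355 with an estimated correlation. By list scores 0 lists passed after adjustment in the exact permutation test, with 6 at an unadjusted p under 0.05. By fry 1 list passed after adjustment, the basophil list. The other lists that passed camera had fry adjusted p of 0.157 to 0.825. The 10 lists not described above, of B and plasma cell, hair follicle, sebaceous, fat, matrix, endothelial, nerve and pigment, cartilage, blood, and Y-linked and Xist genes, had medians of -0.15 to 0.093 and camera adjusted p of 0.202 or more.

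Whether libraries with more basophil marker RNA also held more type 2 RNA was tested within groups. A pooled relation over the 10 libraries had also been planned. It was dropped after the scores were seen, since the basophil scores of the groups formed separate clusters. With each group centred on its own mean, Pearson's r over 10 libraries was -0.222 (permutation p = 0.538, within groups, two-sided) and Spearman's rho was -0.467 (permutation p = 0.176). The basophil score had an SD of 0.346 in CKO and 0.0740 in Flox, so mainly the CKO libraries set this r. With so few libraries a relation is not excluded. Without CKO replicates 1 and 3, the libraries farthest from the median of the centred basophil score, r was -0.364. With scores made from z values per gene, r was -0.0392 (permutation p = 0.897). No other pair of scores was compared.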

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

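The tests of CKO replicate 1 against muscle and a wrong label were chosen after the result was seen. In groups of 5 libraries, 12 of 208 groups tested held 1 library far from the other 4, and chance marks about 1 in 20 groups, or 10.4 here.

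In CKO replicate 1, Aqp9 was at 6.73 FPKM against 9.43 to 10.3 in the other CKO libraries, and Chka at 9.17 against 7.08 to 7.58. In CKO replicate 2, Jund was at 44.9 FPKM against 54.3 to 57.5, Zbtb16 at 1.46 against 5.67 to 8.91, and the mast cell score at 3.78 against 3.43 to 3.51. In CKO replicate 4, Mertk was at 19.1 FPKM against 21.14 to 22.01, and the wound keratinocyte score at 6.52 against 6.65 to 6.70. In Flox replicate 2, Il4 was at 12.8 FPKM against 7.30 to 8.18 in the other Flox libraries, and the macrophage score at 6.79 against 6.91 to 6.95. In Flox replicate 5, Ankrd27 was at 12.0 FPKM against 10.2 to 10.3, and Areg at 15.5 against 19.0 to 20.1. In Flox replicate 4, Spsb1 was at 5.79 FPKM against 4.21 to 4.59.

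CKO replicate 1 stood apart from the other CKO libraries by -3.32 log2 in the median of interferon genes and 1.36 in that of muscle genes. Its interferon and muscle scores were not among the groups marked above. Dilution by muscle would lower immune genes alike. The interferon median lay -2.70 log2 from the pooled T, NK and macrophage median. An interferon difference of its own would give this with or without dilution, so it cannot decide. Mast cell members lay a median of 0.093 from the other CKO libraries, macrophage members -0.077 and T and NK members -0.74. These lists thus did not fall alike. Across genes, which are not independent replicates, the deviation of CKO replicate 1 had a Spearman rho of -0.0707 with transcript length. This was below the 0.1 set beforehand as speaking against RNA degradation as the whole cause. Its Mcpt8 of 6.56 FPKM lay far below the 116 FPKM of the lowest Flox library, against a Flox sample with a wrong label. No biological explanation was tested, and what set this library apart stays open.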

How the results depend on the processing

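Rescaling to equal totals and the muscle covariate were chosen after the result was seen. The 14 genes that passed kept their sign under every alternative run, and Vamp7 stayed between -0.11 and -0.039 without passing. For the 14 genes, whose groups did not overlap, leaving out 1 library could not turn a sign. Against 6 higher and 8 lower genes, the counts were 1 and 2 with no filter on low values, where more genes share the adjustment, 30 and 60 with array quality weights, 2 and 6 after rescaling, and 0 and 0 with the muscle score as a covariate (1267 at an unadjusted p under 0.05 in limma), where the median absolute log2 fold change of the 14 genes was 0.68 against 0.73. Without 1 library in turn they ran from 0 to 11 higher and 0 to 15 lower.

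The labels share only replicate numbers. With the replicate block 0 genes rose and 0 fell in limma (1911 at an unadjusted p under 0.05), where 4 degrees of freedom go to the block. The median absolute log2 fold change of the 14 genes was 0.73 with and without it. A block with 1 library per group and number cannot change these values, so only the calls were lost. Deviations of same-numbered libraries had correlations of -0.210 to 0.212, and of the CKO libraries only replicate 5 correlated best with its own number.

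By camera 9 lists passed, 0 with an estimated correlation, among them no longer the basophil (median -1.03) and eosinophil (-0.40) lists, and 14 with the muscle covariate. Of the lists described, with array quality weights the eosinophil list (-0.32) no longer passed and the interferon list (0.27) did. With the muscle covariate the type 2 (-0.32), interferon (1.30), wound keratinocyte (0.10), macrophage (0.12) and T and NK (0.12) lists passed and the basal keratinocyte list (-0.085) no longer did. The type 2 list also passed with quantile normalization (-0.21). With quantile normalization the type 17 list (0.14) no longer passed and the dendritic list (-0.18) passed, as the latter did with no filter (-0.17). Without a change of call or sign, list medians moved by more than 1.5 times with array quality weights (itch and IgE -0.070, proliferation -0.13, basal keratinocyte 0.038, wound keratinocyte -0.10, dendritic -0.026, barrier -0.14), no filter (mast cell 0.012, type 2 -0.13, macrophage -0.023, vitamin D 0.013), quantile normalization (wound keratinocyte -0.011, macrophage -0.022, vitamin D 0.042), rescaling (wound keratinocyte -0.020, macrophage -0.020, barrier -0.044, vitamin D 0.011) and the muscle covariate (barrier -0.19, beside those given with their lists).

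The following log2 values changed sign, and the cause was not tested. With array quality weights they were Cyp24a1 -0.16, Krt6a -0.049, Ifng 0.0020, Cxcl9 0.24, Cxcl10 0.081, mast cell list -0.073, interferon list 0.27, macrophage list 0.040, T and NK list 0.10. With the muscle covariate they were Cyp24a1 -0.066, Flg -0.093, Cxcl9 0.32, Cxcl10 1.70, mast cell list -0.057, basal keratinocyte list -0.085, interferon list 1.30, wound keratinocyte list 0.10, macrophage list 0.12, T and NK list 0.12, dendritic list 0.075, vitamin D list -0.061. After rescaling they were Krt6a -0.012, mast cell list -0.010, with quantile normalization Krt6a -0.060, and with no filter wound keratinocyte list 0.0053. Without 1 library in turn, values that changed sign ran over Tslp -0.26 to 0.14, Cyp24a1 -0.10 to 0.15, Flg -0.10 to 0.18, Krt6a -0.055 to 0.054, Cxcl9 -0.82 to 0.27, Cxcl10 -0.90 to 0.66, mast cell list -0.064 to 0.060, interferon list -0.32 to 0.55, wound keratinocyte list -0.10 to 0.043, macrophage list -0.048 to 0.056, T and NK list -0.20 to 0.086, barrier list -0.12 to 0.065, vitamin D list -0.0014 to 0.10. Medians of other lists that changed their side of the threshold ran over type 2 -0.29 to -0.14, inflammatory 0.025 to 0.32, neutrophil 0.17 to 0.61, type 17 0.066 to 0.29, dendritic -0.28 to -0.0061. The interferon and T and NK lists passed without CKO replicate 1, and calls of the 14 genes were lost in several of these fits.

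Alternatives that need counts (other scaling factors, other count models) and a stricter filter on low values were not run. The muscle list entered the adjustment over lists under its own score as a covariate, but its value there has no meaning and is not given. Depth is unknown, so what it limits cannot be stated.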

Other observations

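The tests of the basophil pattern, and for the glucocorticoid pattern those of leaving out CKO replicate 1 and of the time of day, were chosen after the result was seen, and the limits by which the tests of a single unusual library, muscle and the time of day were read were changed after their values were seen. Of the limits tried for a single unusual library, 1 also left that question open for the basophil pattern.

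Some glucocorticoid-induced genes, a group that was not among the lists fixed beforehand, had higher values in CKO. A first list of 14 tested genes was built after Fkbp5 and other such genes had been seen, so its median log2 fold change of 0.60 only describes genes picked for it, and 0 of them passed over all genes tested in limma. Zbtb16 was at 5.87 ± 2.81 FPKM in CKO and 1.25 ± 0.325 in Flox (SD, n = 5), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, at 146 ± 61.4 and 67.2 ± 11.2, Klf9 at 29.6 ± 10.3 and 15.3 ± 2.13, and the clock gene Per1 at 16.98 ± 3.59 and 9.13 ± 1.76.

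A glucocorticoid response may be part of this, as a hypothesis. A second list of 16 target genes, written without looking up their values, had a median log2 change of 0.24 (exact permutation p of its score 0.0159), and 0.24 (exact permutation p 0.0159) without Mertk and another gene of the macrophage list, which had been tested before. The p-values of the added lists were not adjusted over lists. Of the 16 genes, 2 rose adjusted over the list alone, and the groups were without overlap for 0. The lowest adjusted p of a member over all genes tested was 0.116 (limma). Without CKO replicate 1 the median of the first list went from 0.60 to 0.37 and that of the second to 0.12 (exact permutation p 0.0238), so how much that library adds stays open. With the muscle score as a covariate the first median was 0.34 and the second 0.064, so a share from muscle cannot be told apart from the group with 10 libraries. Of 8 clock-controlled genes (median -0.085), 2 had a positive log2 fold change and 2 fell adjusted over the list alone, so another time of day stays open, as do stress and handling.

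The lower basophil marker RNA was weighed in the same way. The pooled median of mast cell, T, NK and macrophage genes was -0.044, against dilution of immune RNA as the cause. The basophil median was -0.89 without CKO replicate 1 and -1.01 without Mcpt8, against that library or that gene alone. The exact permutation p of the score without that library was 0.00794. Since the scores of the groups do not overlap, leaving out any CKO library gives this smallest p, so it decides nothing about CKO replicate 1. Fewer basophils and less marker RNA per basophil cannot be told apart, since the CKO to Flox ratios of Mcpt8, Prss34, Cd200r3, Cyp11a1 and Itga2b spread over 2.47 times and other skin cells could add a base level to some of them. A difference that came with the samples, such as a batch or the Cre driver itself, was not tested.

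The count of genes changed at the adjusted threshold was compared with that of other splits of the same libraries. Of 100 splits of the libraries into 5 and 5, drawn with a fixed seed, only 1, the real one, gave as many as 14 genes, and the highest other gave 4. At an unadjusted p under 0.05 the real split gave 1993 genes and the highest other 2134, so that 2 splits, the real one included, gave as many. The other splits mix CKO and Flox libraries, so a group difference widens their spread and lowers their counts. A count of 14 was thus rare among the splits, but chance was not excluded.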
